A study of Homo sapiens with 3 samples.

How the data were processed

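Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in THP1, a human monocytic leukaemia line, after 24 h with the phorbol ester PMA, which drives these cells towards a macrophage-like state. The 3 samples were 1 library for acetylated lysine 27 of histone H3 (H3K27ac), 1 for the deacetylase SIRT1 and 1 input. A peak list was used for each of the 2 antibodies; signal of the input was not analysed here. With 1 library per antibody there is no replicate check, and no p-value across peaks or genes was computed.

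Per the submitters' processing notes, MACS2, deepTools and the build hg38 were used; versions, the aligner and the control given to the peak caller are not given in the sources used here. Peak names carry the output label of a duplicate-marking step. The fold at each summit, a ratio to the local background, is the authors' value from the peak caller. The −log10 p and −log10 q of each peak were likewise deposited by the authors. The deposited score was 10 times −log10 q in the H3K27ac list and 10 times −log10 p in the SIRT1 list, cut to a whole number, in 100% of the peaks of each. The smallest −log10 q in the H3K27ac list was 1.30. In the SIRT1 list the smallest −log10 p was 2.00 and the smallest −log10 q was 0, so the lists were filtered on different quantities. Scores and folds were used within their own list only.

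The number of fragments at each summit and the background rate were recovered from fold and −log10 p, taking fold as fragments plus 1 over background plus 1 and p as a Poisson tail. Within the rounding of the deposited values, 99.996% of H3K27ac peaks and 99.999% of SIRT1 peaks had exactly 1 whole-number solution. On simulated peaks the step returned the true number in 100% of 1997 H3K27ac-like and 100% of 1786 SIRT1-like cases. The lowest background rate was 0.937 fragments for H3K27ac and 0.362 for SIRT1, a ratio of 2.59, and is called the floor of each list. Total read numbers are not given in the sources used here.

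Comparisons used chromosomes 1 to 22, X and Y. Overlap meant at least 1 shared base. Chance placement came from 100 shuffles of the SIRT1 peaks within their chromosome, leaving out 1-Mb bins with no peak and no gene. Peaks placed by this same shuffle gave an observed over shuffled ratio of 0.999. That checks the computation and not whether the shuffle is the right model of chance. Intervals are 95% exact binomial or Poisson intervals and cover counting error only. The planned promoter, exon, intron and motif classes need strand, exons and sequence, which were not used here. In their place a gene end was taken as 1 kb on both sides of either end of a protein-coding gene record (20037 genes, assembly GRCh38), so a start cannot be told from a stop.

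The 19 lists of 20 genes, the tests and most alternatives were fixed before the data were examined. Each list was set beside 10000 random lists of the same size, for SIRT1 with the same number of acetylated genes. Named genes were SIRT1, SPI1 and NFKB1; per list, up to 3 with the highest SIRT1 fold and up to 2 with the highest H3K27ac fold and no SIRT1 peak; the 5 highest of all genes in each class; and the gene nearest each of the highest domains. Other genes named were chosen after their values were seen. Some genes that the rule selects are not reported here. The gene end definition, the comparison of acetylated and other ends, the split by background, the shift of 20 to 100 kb and the restriction by q or fragments were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.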

Results

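H3K27ac, a mark of active promoters and enhancers, and the NAD-dependent deacetylase SIRT1 were mapped in PMA-treated THP1 cells, each in 1 library. The H3K27ac list held 50268 peaks and the SIRT1 list 96805, of which 48735 and 95517 lay on the primary chromosomes. H3K27ac peaks had a median width of 682 bp and covered 58.0 Mb, and SIRT1 peaks had a median width of 301 bp and covered 33.8 Mb. The median fold, the authors' own value, was 6.36 for H3K27ac and 2.78 for SIRT1, each relative to its own background.

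H3K27ac marked an end of 11354 of 20037 protein-coding genes, among them genes that macrophages use. At SPI1, which encodes the macrophage transcription factor PU.1 (hg38 chromosome 11, 47354860 to 47378547), the strongest peak at a gene end spanned 47372444 to 47379714 with a fold of 109. NFKB1, an NF-kB subunit gene on chromosome 4, had a peak from 102500245 to 102503552 with a fold of 74.4. SIRT1 itself, on chromosome 10, had an H3K27ac peak from 67883705 to 67885790 with a fold of 50.9 and no SIRT1 peak at its ends.

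Of the 20 macrophage identity genes, 16 carried H3K27ac at a gene end, against a mean of 11.3 in random lists, and 248 of 10000 random lists had as many. FCER1G, an Fc receptor subunit gene, had a fold of 98.8. CD163, MRC1, LYZ and CD36 had no H3K27ac peak at a gene end. Of the NF-kB and inflammatory genes 19 of 20 were acetylated, with RELB at a fold of 93.9, and IL6 was the exception. The AP-1 and early response list had 18 of 20, led by JUNB at 81.5 and JUND at 77.1.

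Cholesterol and lipid genes were acetylated in 19 of 20 cases, with the cholesterol exporter ABCA1 at a fold of 78.4 and the lipid droplet gene PLIN2 at 59.9. All 20 autophagy and lysosome genes carried the mark, with ATG7 at 99.1 and SQSTM1 at 72.6. All 20 oxidative phosphorylation genes, all 20 cytosolic ribosomal protein genes and all 20 histone acetyltransferase and deacetylase genes did too, with COX4I1 at 40.9, RPS19 at 47.5 and KAT5 at 73.4. The sirtuin and NAD list had 16 of 20, with the acetyltransferase gene EP300 at 156. The interferon list had 15 of 20, glycolysis and cell cycle 17 each, and circadian clock 13, a number reached by 3053 of 10000 random lists.

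Among markers of other cell types 23 of 120 genes carried H3K27ac, and in the lists above 230 of 260 did; the difference between these groups was not tested. Set beside random lists of all genes, as few were found in 413 of 10000 for B cell, 152 for epithelial, 8 for T and NK cell, 1 for erythroid and 0 for neuron and hepatocyte markers. The mark was found at 7 B cell, 6 epithelial, 4 T and NK cell, 3 erythroid, 2 neuron and 1 hepatocyte gene of 20 each. The hepatocyte gene was SERPINA1, with a fold of 34.1. Of 392 olfactory receptor genes, 7 carried H3K27ac, against a mean of 222 in random lists.

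**Figure D1:**
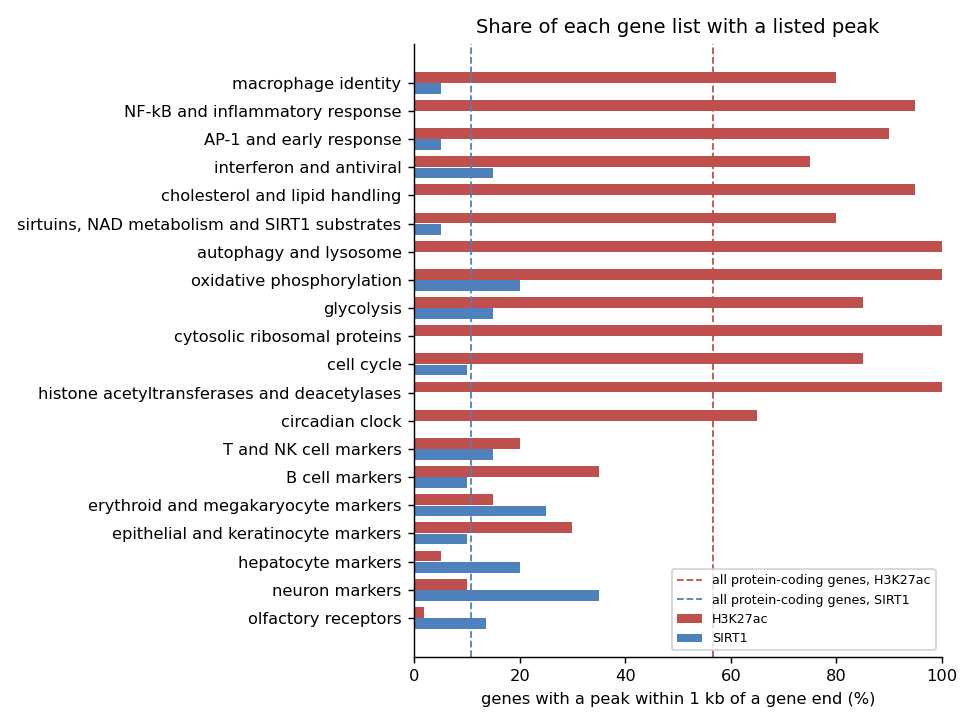
Share of each gene list with an H3K27ac peak (red) or a SIRT1 peak (blue) within 1 kb of a gene end, in percent; dashed lines are the shares among all 20037 protein-coding genes, 56.7% and 10.8%. H3K27ac reached 100% in 4 lists and 5% in hepatocyte markers, while SIRT1 did not follow the same order.

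In all, 21.9% of H3K27ac peaks had their summit within 1 kb of a gene end, 7.76 times the shuffled share, and 11354 of 20037 genes were marked. These peaks had a median fold of 14.7, against 5.55 inside genes and 5.77 outside. The highest fold at a gene end without SIRT1 was 210 at ACTR3, an actin nucleation gene, followed by ATXN2L at 206 and ZMYND8 at 168.

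Stitching H3K27ac peaks within 12.5 kb gave 19489 domains. The highest spanned 293 kb over ZMIZ1 on chromosome 10, from 79063270 to 79356510, with 79 peaks. Domains over GTF2IRD1, RAPGEF1, AHRR, MBP, ATG7, RGS16 and DOT1L were also among the highest, as was 1 located 19778 bp from MTSS1. The domain of rank 13 ran from 47358454 to 47427645 over SPI1 and held 25 peaks. CEBPB and CSF1R, chosen after their values were seen, were the nearest genes at ranks 12 and 19. SIRT1 peaks lay in 11 of the 20 highest domains, against a mean of 18.7 after shuffling.

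**Figure D2:**
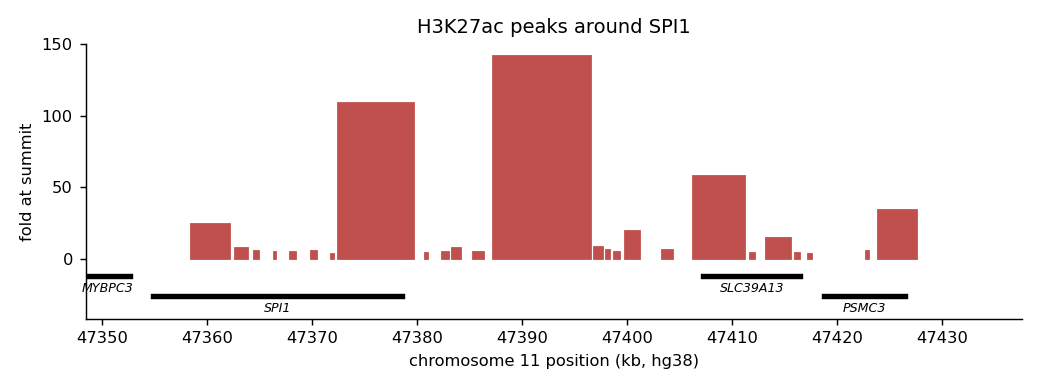
H3K27ac peaks around SPI1 on chromosome 11 (hg38, position in kb); each box is a peak drawn to its width, with its height the fold at the summit, and black bars are protein-coding gene records. The tallest box, at a fold of 141, lies outside the SPI1 record, and 0 SIRT1 peaks fell in the view.

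The SIRT1 list rested on few fragments. At the summit, 39.8% of peaks had 2 fragments and 44.6% had 3, whereas the median H3K27ac peak had 15. A q of at most 0.05 was reached by 144 of 96805 SIRT1 peaks, or 0.149%, and −log10 q was 0 for 86.3%. The peak with the highest −log10 q, 13.7, lay on an unlocalised contig of chromosome 22, with a fold of 2.40 on a background of 60.6 fragments. Of the 136 peaks with a q of at most 0.05 on the primary chromosomes, 24 had a background over 2 floors. Genes named for SIRT1 below therefore mostly have peaks that did not pass that q.

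**Figure D3:**
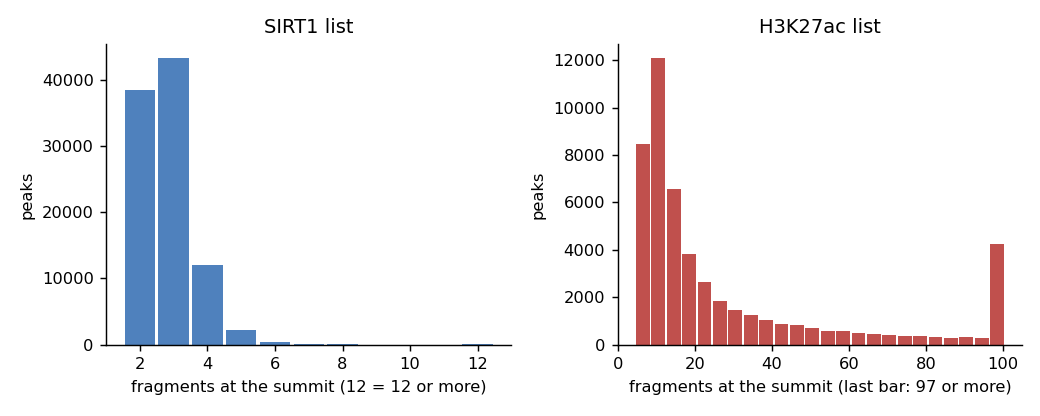
Number of peaks (vertical axis) by fragments recovered at the summit (horizontal axis), SIRT1 on the left and H3K27ac on the right; the last bar of each panel collects all higher values. SIRT1 peaks cluster at 2 and 3 fragments, with a median of 3, and H3K27ac peaks have a median of 15.

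SIRT1 peaks lay at an end of 2173 genes, against 2762 after shuffling. Among acetylated genes the highest was BATF3, an AP-1 family gene on chromosome 1, with a fold of 4.62 on 6 fragments at 212686442 to 212686778; its −log10 q was 0.804. PRELID3A followed at 4.52 and INHA at 4.32. Without H3K27ac the highest were PRAMEF26 at 5.87 on 7 fragments, and CSH2 and the NADPH oxidase gene NOX4 at 5.14 on 6 fragments each. These 3 genes were the ones with a peak that reached a q of 0.05 at a gene end.

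Of the 380 list genes 38 had a SIRT1 peak and 11 had both marks, though not always at the same end. Within 1 kb of a gene end, the NF-kB, cholesterol, autophagy, ribosomal protein, histone modifier and circadian lists had 0 SIRT1 peaks, against means of 1.53 to 2.06 in random lists of like acetylation. Between 1120 and 2031 of 10000 such random lists also had 0. Oxidative phosphorylation genes had 4, with NRF1 at a fold of 2.94 and ATP5F1B at 2.80, and glycolysis genes had 3, with PGAM1 at 2.91. SIRT1 lay at the acetylated end in 1 of the 4 and 0 of the 3. At NRF1, ATP5F1B and PGAM1 it lay at the other end. Random lists of like acetylation had means of 1.54 and 1.76, and 643 and 2517 of 10000 had as many. Neuron markers had 7, with NEFL at 3.10, against a mean of 2.87 in random lists of like acetylation. Of 10000 such lists 170 had as many, which was the lowest number among the 20 lists compared and was not corrected for that choice. The neuron count moved to 4 with a gene end window of 500 bp and 11 with 2500 bp. It was 1 for SIRT1 peaks on at least 4 fragments and 0 with a fold of at least 4.

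The series paired both maps, so their overlap was compared. SIRT1 peaks were fewer inside H3K27ac peaks than chance placement gave: 712 of 95517, or 0.745% (95% interval 0.692 to 0.802), against 2.56% after shuffling, a ratio of 0.291. In the other direction 1.45% of H3K27ac peaks overlapped a SIRT1 peak, against 4.83%. Genes with both numbered 875, against 1231 for independent lists. At the 9644 genes acetylated at only 1 end, SIRT1 lay at the acetylated end of 130 and at the other end of 695. The median SIRT1 fold was 2.78 with and without H3K27ac, a coarse measure with 84.4% of SIRT1 peaks on 2 or 3 fragments. By fragments at the summit, the share overlapping H3K27ac was 0.665% (0.586 to 0.752) at 2 and 0.731% (0.652 to 0.816) at 3. It was 0.963% (0.795 to 1.16) at 4, 0.976% (0.612 to 1.47) at 5 and 1.43% (0.741 to 2.49) at 6 or more.

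The ratio differed with the recovered background of the H3K27ac peak. Against shuffles within the chromosome it was 0.730 (0.616 to 0.858) at peaks on the background floor and 0.0858 (0.0597 to 0.119) at peaks over 3 floors. Against shifts of 20 to 100 kb, chosen after seeing the data, it was 1.05 (0.887 to 1.24) at the floor and 0.114 over 3 floors. The floor peaks thus lay below chance by the planned shuffles and not by the added shifts.

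**Figure D4:**
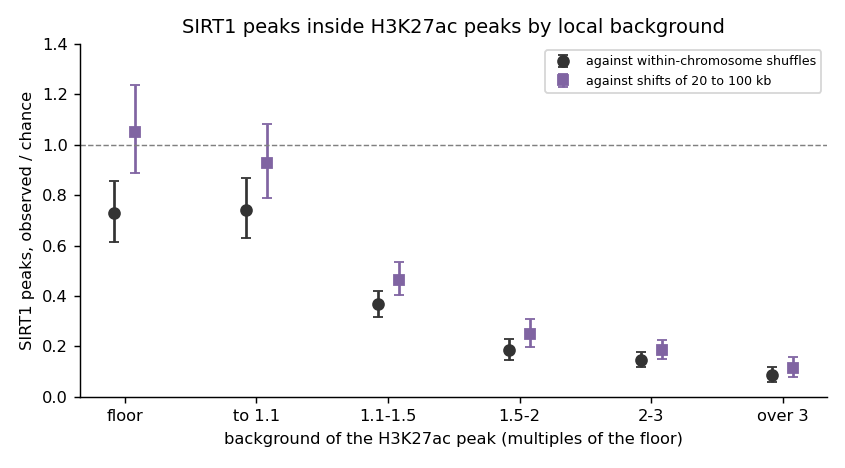
SIRT1 peaks inside H3K27ac peaks as a ratio of observed to chance (vertical axis) by the background of the H3K27ac peak in multiples of the floor (horizontal axis); bars are 95% Poisson intervals and cover counting error only. Circles, against shuffles within the chromosome, fall from 0.730 to 0.0858; squares, against shifts of 20 to 100 kb, fall from 1.05 to 0.114.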

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

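A signal in parts of the lists that no comparison used was found on contigs outside the primary chromosomes. They held 1533 H3K27ac peaks, 551 of them on alternate contigs of chromosome 6, and 1288 SIRT1 peaks.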

How the results depend on the processing

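In every setting run the ratio of observed to shuffled overlap stayed below 1, and the number of acetylated genes stayed within 1.5 times the reported one. The strictest setting left too few SIRT1 peaks to bear on the ratio, and so did a q of at most 0.05, with 1 overlapping peak. The SIRT1 counts did not keep their size. The cause of the changes below was not tested.

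With a −log10 q of at least 5, only 2 SIRT1 peaks were left, with a median width of 281 bp; the median H3K27ac width was 1039 bp and 28.1% of H3K27ac peaks lay at gene ends. Those 2 SIRT1 peaks gave 0% overlap in both directions, 0 as observed over shuffled, 0% at gene ends, and 0 genes, 0 genes with both, 0 list genes and 0 list genes with both. With a fold of at least 4, 1527 SIRT1 peaks of median width 371 bp were left and the median H3K27ac width was 837 bp. Then 1.05% of SIRT1 peaks overlapped H3K27ac (0.418 of shuffled) and 0.0388% the other way (0.414). Gene ends held 24.4% of H3K27ac and 1.64% of SIRT1 peaks, with 34 SIRT1 genes, 11 with both, 1 list gene with SIRT1 and 1 with both. SIRT1 at the acetylated over the other end was 0.286, against 0.187 reported.

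With the 20000 strongest peaks of each list, 0.29% overlapped in each direction, at 0.160 and 0.163 of shuffled, with 482 SIRT1 genes and 138 with both. Ties in −log10 q made −log10 p the ranking for SIRT1. Overlap of at least 50% of the peak gave 0.572% of SIRT1 and 0.337% of H3K27ac peaks, the latter at 0.543 of shuffled. Overlap of at least 50% of both gave 0.144% at 0.542 and 0.283% at 0.545. Merging within 1 kb gave 2.12% of H3K27ac peaks.

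A gene end window of 500 bp gave 17.5% of H3K27ac and 1.004% of SIRT1 peaks, 1257 SIRT1 genes, 440 with both, 25 list genes with SIRT1, 7 with both, and 0.0857 for acetylated over other ends. A window of 2500 bp gave 28.4% and 4.77%, 4606 SIRT1 genes, 2274 with both, 76 list genes, 31 with both, and 0.379.

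The following settings were chosen after seeing the data. Shifts of 20 to 100 kb gave ratios of 0.383 and 0.391. Keeping the 136 SIRT1 peaks with a q of at most 0.05, of median width 423 bp, gave ratios of 0.270 and 0.267. They rested on 1 overlapping SIRT1 peak, and in separate shuffles the first ratio had an interval of 0.00627 to 1.38, which includes 1. This setting gave 0.00205% of H3K27ac peaks, 1.47% of SIRT1 peaks at gene ends, 3 genes, 0 with both, 0 list genes and 0 list genes with both. SIRT1 peaks on at least 4 fragments gave 0.991% overlap at 0.370 and 0.304% at 0.369, with 371 genes, 139 with both, 6 list genes, 1 with both, and 0.245 for acetylated over other ends. Whole gene records with 1 kb on both sides gave 12930 acetylated genes, 10562 SIRT1 genes, 7143 with both, 164 list genes and 105 with both. No number for independent lists was set beside the 7143. The lower count of genes with both than for independent lists, 875 against 1231, was therefore shown for gene ends only.

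The alternatives with 1 start per gene and those for motifs were not run, since strand and sequence were not used here. The median −log10 q of SIRT1 peaks was 0 with and without H3K27ac, so no ratio was formed. No paired analysis was possible because no comparison of replicate groups was made. Of the SIRT1 peaks, 84.4% rested on 2 or 3 fragments; whether sequencing depth, enrichment or the threshold sets this was not tested.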

Other observations

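The tests here were chosen after the results were seen, except that the prediction for peaks of like width and fold was written before its result. The split by background used in it was itself chosen after seeing the data.

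SIRT1 peaks were fewer inside H3K27ac peaks than after shuffling. At H3K27ac peaks of like width and fold, the ratio was 0.968 (0.737 to 1.25) on the background floor. It was 0.0921 (0.0537 to 0.148) above 1.5 floors, so a raised background may account for part of the deficit. That background was recovered from the H3K27ac list, and at like fold a higher background means more H3K27ac fragments. The test therefore cannot tell a raised background from more H3K27ac signal. By width, floor peaks had ratios of 1.19 (0.868 to 1.59) in the narrowest tertile, 1.05 (0.785 to 1.38) in the middle and 0.448 (0.332 to 0.593) in the widest. Against shifts of 20 to 100 kb they were 1.57 (1.14 to 2.10) and 1.43 (1.07 to 1.88), an excess of SIRT1 peaks, and 0.683 (0.505 to 0.902). Background at the summit thus did not account for the deficit in the widest tertile. Those peaks had a median width of 1232 bp, and a raised background away from their summits was not tested. Placement at scales over 100 kb was not the whole cause either, with a ratio of 0.383 against those shifts, and lower SIRT1 occupancy of acetylated chromatin stayed open: only 4.04 overlaps were expected among peaks past a q of 0.05, in a set of shuffles separate from that behind the ratio of 0.270 for these peaks, and 1 was seen.

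On chromosome 1 from 39000001 to 43000000, the background of H3K27ac peaks had a median of 10.7 floors, against 1.55 elsewhere. For SIRT1 peaks the median was 4.26 floors, against 1 elsewhere. In the whole stretch, 78.9% of SIRT1 and 91.0% of H3K27ac peaks lay above 2 floors, which missed the bound set for extra copies. That bound was set after the data were seen, and the stretch was cut at 1-Mb borders. The 18 H3K27ac and 16 SIRT1 peaks not above 2 floors all lay in the first 1 Mb. Extra copies starting inside that bin would miss the bound too, so the test decides neither for extra copies nor for scattered repeats. Leaving out that bin, after the first test had failed, gave 100% for both lists by construction, so it decides nothing and extra copies and repeats cannot be told apart for the rest.

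In 2 intervals with genes neither list had a peak: chromosome X from 42006563 to 45134571, with KDM6A and MAOA among 8 genes, and chromosome 9 from 21255566 to 22251717, with CDKN2A, CDKN2B and MTAP among 11. The intervals were picked from these same lists for being empty, and the shuffles took no account of where reads can be mapped. Within those limits, chance by uniform placement was argued against, since 0 of 100 shuffles left either without a SIRT1 peak. Shuffles gave a mean of 34.8 in the chromosome 9 interval. The part from MTAP on, which holds no interferon gene, had 0 peaks against 15.6 by shuffling. Any part of an interval picked for being empty has 0 peaks, so this cannot decide on reads shared among interferon alpha genes. Loss of both regions in this line may be a candidate explanation, and it cannot be told apart from poor mapping without read depth. The gene names were chosen after their values were seen.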
